A study of Sus scrofa with 6 samples.

How the data were processed

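RNA sequencing libraries of hypothalamus, pituitary and ovary from estrous and anestrous primiparous sows were compared, 6 libraries in all, with 1 library for each tissue and state. Per the labels' protocols, tissue was frozen, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. TopHat2 2.1.0 was among the tools used, per the submitters' processing notes. The read counter, the genome build, the annotation release and whether counting used strand were not given in the sources used here, so genes that overlap, or that share reads with a near-identical copy, are uncertain. The deposited files hold 1 table per tissue with the normalised signal of each Ensembl pig gene in both libraries, and, per the file headers, the authors' p-value and adjusted p-value for that pair of libraries, and DESeq is named per the labels. The deposited signal is a read count divided by a size factor of the library. Every value above 0 was a whole multiple of the column's smallest value within 0.01 of a read (100% of values), so the reads of each gene were recovered by dividing by that value. Library totals of these reads lay between 15314325 and 17384789. The 10 genes with most reads held 20.3% and 21.9% of them in the hypothalamus (estrous and anestrous), 33.3% and 35.9% in the pituitary, and 8.55% and 11.5% in the ovary. Tables were normalised separately, so folds were taken only within a tissue.

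The comparison is 1 library against 1, so no test of the states was made per tissue, and p-values are the authors' only. They measure 2 libraries, not the states. Gene symbols came from the deposited tables (12762 of 19465 genes) and then from a table of Ensembl pig gene names, which together named 14419 genes. Where both sources had a name, 555 of 9651 differed, and the tables' own was used. Of the reproductive genes fixed beforehand, PDYN, NPVF, LHB, INHBB, CYP11A1, AMH and PTGS2 were not found by name and were not analysed here.

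The log2 fold was log2 of the anestrous over the estrous normalised count, each with a pseudocount of 1, which understates the difference of genes with few reads. Folds in the text are ratios without a pseudocount. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals from the reads. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules and animals were not replicated. Where a library had 0 reads, the fold was computed against a floor of 3 reads in that library and is given as "at least". It is not a 95% limit: for PPP1R11 in the hypothalamus it was 40.9, while the lower 95% counting limit was 32.8. A gene was counted as higher or lower when its mean normalised count was at least 50 and its log2 fold, with the pseudocount, at least 1 in size, here called 2-fold. For gene lists, the median log2 fold of members with a mean of at least 10 (at least 4 members), which were counted as 2-fold different by the same log2 fold but with that lower floor, was placed among 10000 random lists of the same size matched on 20 bins of mean expression. A list below percentile 2.5 or above percentile 97.5 stood apart within these libraries. Red blood cell genes had under 4 measured members in each tissue, so they got no median.

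The 34 gene lists, their assignment to tissues, the counting rules and the rule for named genes were chosen before the data were examined. Lists were reported for the tissues they were assigned to. Lists that stood apart in a tissue they were not assigned to are mostly left out. Named genes were, per tissue, the 10 with the highest and the 10 with the lowest log2 fold among named genes over the floor, the fixed genes of the reproductive axis, up to 4 members of each list, over the floor of 50, with the largest absolute log2 fold, and named genes at least 2-fold different the same way in all 3 tissues. Some genes that this rule names are not reported here. Other genes, where named, were chosen after their values were seen. Alternatives were equal library totals, a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed), a pseudocount of 5, no floor, a floor of 200, and the authors' adjusted p of at most 0.05 as a further condition. Alternatives added after the data were seen were a count test on the recovered reads, the comparison without the hypothalamus libraries, and the lists without genes that differed alike in all 3 tissues. The count test used edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 in R 4.3.3, with tissue as a block and state as the tested term. It treats the tissues as replicates of a state, which they are not, and it was kept out of the main results.

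The counting rule was tested on simulated reads drawn from the real means with 200 genes changed. These reads carried counting (Poisson) error only and were scaled by the trimmed mean of log ratios. It recovered 97%, 99% and 98% of 4-fold changes among 11381, 10725 and 10890 genes over the floor in hypothalamus, pituitary and ovary, and called 0 unchanged genes. Of 100 random unchanged lists, 4, 4 and 3 stood apart. Recovery of 2-fold changes by the counting rule was not computed. Since the simulated reads held no variation between animals, they cannot show how often the rule or the lists err in the real libraries. The edgeR step, simulated over 14540 genes with a dispersion of 0.05, recovered 46% of 2-fold and 100% of 4-fold changes and called 3 unchanged genes. The real libraries were noisier (biological coefficient of variation 0.291), so these shares overstate the power of this step. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.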

Results

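RNA was sequenced from the hypothalamus, the pituitary and the ovary of Landrace x Large White sows after their first litter (primiparous sows), taken either in estrus or in an anestrus that the labels put down to inactive ovaries. The comparison asks which genes of this reproductive axis differ in expression between the states. There were 6 libraries, 1 per tissue and state. The labels give 3 sows per state and do not say whether the RNA of the sows was pooled. The reads assigned to genes numbered 15314325 in the estrous and 15812041 in the anestrous hypothalamus library, 17010663 and 17384789 in the pituitary libraries, and 15487425 and 16436816 in the ovary libraries. Each table listed 19465 genes, of which 15182 to 15591 had a read in a given library. With 1 library per tissue and state, no difference reported here has a replicate check. Every value describes these libraries, "higher" and "lower" mean the anestrous library relative to the estrous one, and every 95% interval or 3-read floor covers counting error only.

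In the hypothalamus, several neuropeptide genes were among the genes with the lowest anestrous to estrous ratios. AVP (ENSSSCG00000007163), the precursor of vasopressin, gave 13729 reads in estrus and 435 in anestrus, which made its normalised read count 30.6-fold lower (95% interval 27.8 to 33.7). OXT, the precursor of oxytocin, gave 4007 and 572 reads and was 6.79-fold lower (6.22 to 7.42). POMC, the precursor of melanocortins and beta-endorphin, gave 4697 and 744 reads and was 6.12-fold lower (5.66 to 6.62). KISS1, whose product kisspeptin stimulates GnRH neurons, gave 139 and 23 reads and was 5.86-fold lower (3.75 to 9.54). GNRH1, which encodes the releasing hormone of the gonadotropins, gave 70 and 28 reads and was 2.42-fold lower (1.54 to 3.90). Beside these, 13 of 14 thalamus markers, a list added after the data were seen, were higher (median log2 fold 0.85, percentile 100).

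Of 10 measured genes for reproductive neuropeptides and their receptors, 2 were at least 2-fold lower, none was 2-fold higher and 8 stayed within 2-fold by the log2 fold with its pseudocount, GAL among them (354 and 171 reads, 2.01-fold lower without it). Their median log2 fold was -0.45, at percentile 0.39 of random lists matched on expression, and it was -0.15, inside the random range, when genes below a mean of 200 were left out. TAC3, which encodes neurokinin B, was 1.43-fold lower (1.28 to 1.60), TACR3 had a log2 fold of -0.69 and NTS one of 0.79. The list of releasing and neurosecretory hormones did not stand apart (median -0.09, 8 genes, percentile 13.4). Of its genes, 3 were at least 2-fold lower, AVP, OXT and GHRH (-2.60), and none was 2-fold higher, with TRH at 0.48 and CHGB at 0.32. Appetite genes did not stand apart either (median -0.07, 12 genes, percentile 22.4). HCRT (orexin) was 2.52-fold higher (2.38 to 2.68) and PMCH (melanin-concentrating hormone) 2.02-fold higher (1.94 to 2.09). NPY gave 22 reads in estrus and 3 in anestrus, a 7.11-fold lower count with a counting interval of 2.13 to 37.1. AGRP gave 22 reads and 1 read, 21.3-fold lower with an interval of 3.45 to 880. ESR1 was 1.27-fold lower (1.03 to 1.56). PGR had 14 and 12 reads, too few to show a difference. The steroid hormone receptors had a median of -0.23 over 9 genes (percentile 8.39).

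Immediate early genes, which respond quickly to neuronal activity and other stimuli, were lower in all 16 measured cases, 7 of them at least 2-fold (median log2 fold -0.80, below all 10000 random lists). ATF3, NR4A3, BTG2 and EGR1 had log2 folds of -1.26, -1.25, -1.22 and -1.22. Markers of neurons were higher in 10 of 10 genes, each by less than 2-fold (median 0.49, above all random lists), with SLC32A1 at 0.83 and SYT1 at 0.59. Myelin genes were lower in 7 of 7, each by less than 2-fold (median -0.34, percentile 0.02), with OPALIN at -0.56. Choroid plexus and ependyma genes had a median of -0.67 (8 genes, 6 of them lower, percentile 0.01), with OTX2 at 0.67 but the lowest values for TTR, the carrier of thyroid hormone, at -1.38 and the potassium channel gene KCNJ13 at -1.11. Among 7 microglia genes the median was -0.27 (percentile 0.30), with P2RY12 at -0.78 and CX3CR1 at -0.60 but CSF1R at 1.70. T and B lymphocyte genes (median -0.78, 7 genes, percentile 0.495), with CD2 at -1.10, and interferon-stimulated genes (median -0.60, 16 genes, below all random lists), with OAS2 and USP18 both at -1.21, also stood apart as lower. Astrocyte (-0.08), anterior pituitary hormone (-0.08), cell cycle (-0.13), cholesterol (0.11), endothelium (0.02), MHC class II (-0.17), heat shock (0.19), unfolded protein response (0.00) and glycolysis lists (0.07) had medians inside the random range.

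Among all 11390 hypothalamic genes with a mean of at least 50, 147 were at least 2-fold higher and 119 at least 2-fold lower. With the totals of the libraries made equal, which moved every log2 fold in this tissue by -0.09, the counts were 113 and 167. Among genes with a symbol, those lower by the most were SQRDL (162 reads in estrus and 1 in anestrus, 157-fold, interval 27.8 to 6237), AVP, SLC6A3, the dopamine transporter (286 and 12 reads), the tubulin gene TUBA1C (5943 and 404 reads), the myosin-binding protein gene MYBPC3 (log2 fold -3.37), OXT, the chemokine gene CXCL10 (-2.68), POMC, KISS1 and the keratin gene KRT19 (-2.39). Those with a symbol that were higher by the most were C14H10orf116 (1 and 260 reads, 268-fold, interval 47.7 to 10640), PPP1R11 (0 and 119 reads, at least 40.9-fold), E2F7 (6 and 366), SNCG (2 and 137), RGS16 (22 and 667), NEXN (log2 fold 3.18), KITLG (3.12), SHOX2 (2.88), GABRD (2.66) and SMARCC2 (2.60). PPP1R11, ESR1 and RAB11FIP5 each occur at 2 places in the tables, so that reads may be divided between copies. In the authors' deposited table, 118 genes had an adjusted p of at most 0.05. Adjusted p in the authors' deposited table was 3.29e-36 for AVP, 1.04e-16 for OXT, 7.64e-15 for POMC, 0.00399 for KISS1 and 1 for GNRH1.

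**Figure D1:**
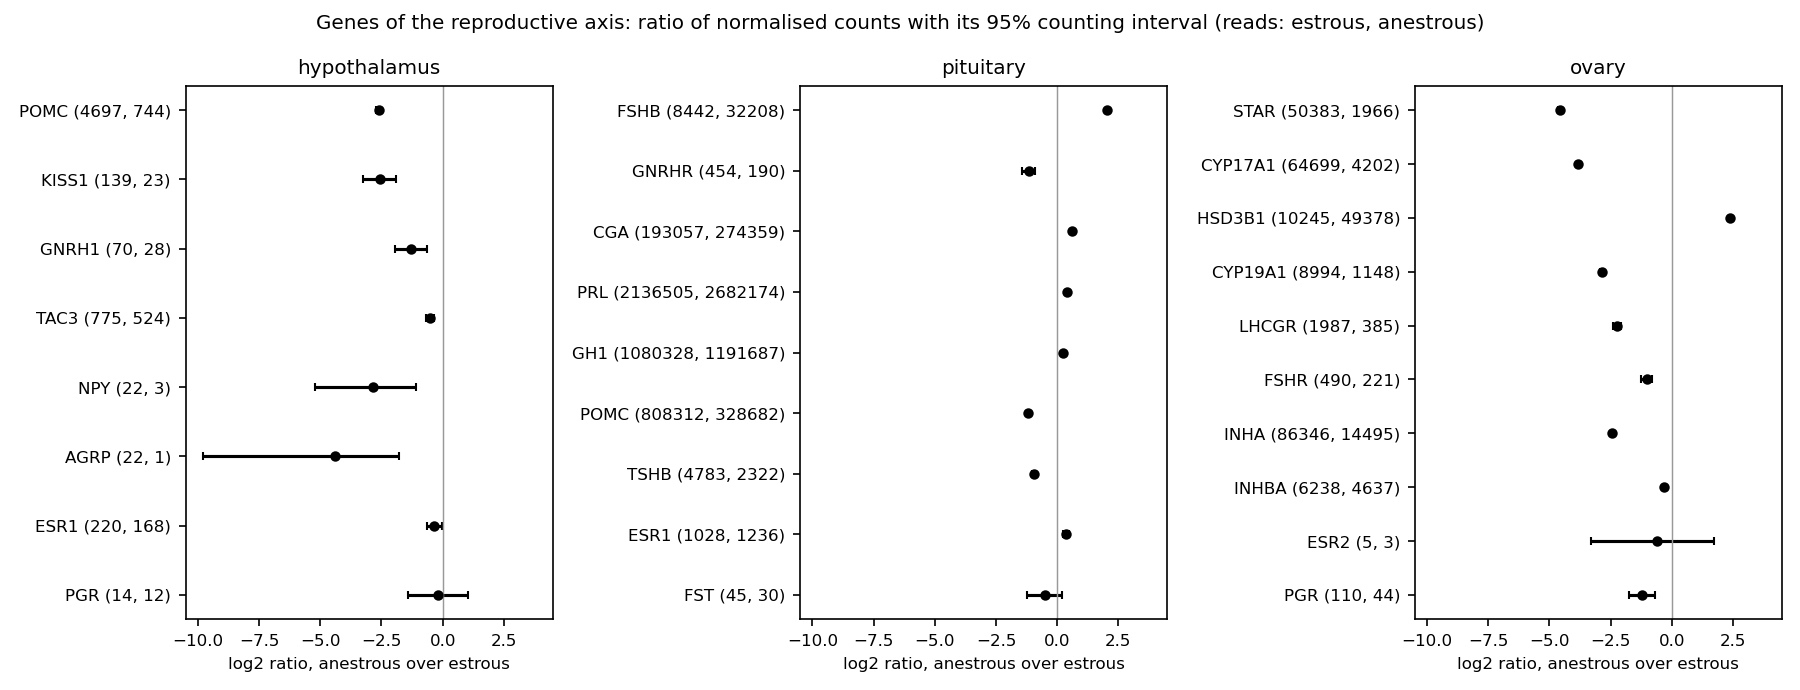
Genes of the reproductive axis fixed beforehand, 1 panel per tissue, with the log2 ratio of normalised read counts (anestrous over estrous library) on the x axis and the reads of both libraries beside each symbol. Points are single ratios and bars are 95% counting intervals; FSHB (4.04-fold higher) and HSD3B1 (5.22-fold higher) lie to the right, and STAR and CYP17A1 far to the left.

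In the pituitary, the beta subunit of follicle-stimulating hormone was higher and most measured receptors for hypothalamic hormones were lower. FSHB (ENSSSCG00000013328) gave 8442 reads in estrus and 32208 in anestrus, a 4.04-fold higher normalised count (3.95 to 4.14). CGA, the alpha subunit shared by the glycoprotein hormones, was 1.51-fold higher, PRL (prolactin) 1.33-fold higher and GH1 (growth hormone) 1.17-fold higher. POMC gave 808312 and 328682 reads and was 2.32-fold lower (2.31 to 2.33), and TSHB, the thyrotropin beta subunit, was 1.94-fold lower (1.85 to 2.04). As a list, the 6 hormone genes had a median log2 fold of 0.32 (percentile 98.8), with 1 at least 2-fold higher and 1 at least 2-fold lower.

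Of 9 measured receptors for hypothalamic hormones, 5 were at least 2-fold lower and none was 2-fold higher (median -1.17, below all random lists). AVPR1B, the vasopressin receptor of corticotrophs, gave 1685 and 398 reads, and CRHR1, the receptor for corticotropin-releasing hormone, was at a log2 fold of -1.59. GNRHR gave 454 and 190 reads and was 2.25-fold lower (1.90 to 2.69), while the dopamine receptor DRD2 was at 0.27. Steroid hormone receptors had a median of -0.35 (9 genes, percentile 1.69), with GPER1 at -1.67, NR3C1 (glucocorticoid receptor) at -1.23 and PGR at -0.92, but ESR1 was 1.27-fold higher (1.17 to 1.39). Genes of the activin, inhibin and follistatin system had a median of 0.27 (9 genes, percentile 97.7), each within 2-fold. They fell inside the random range with a pseudocount of 5 (0.25). The activin receptor gene ACVR1B was at 0.66 and TGFBR3 at 0.65. FST, which encodes the activin-binding protein follistatin, had 45 and 30 reads, and its ratio (0.706, interval 0.430 to 1.15) did not exclude equal levels. Pituitary transcription factors had a median of 0.05 (10 genes, percentile 62.2), with GATA2 at 0.57.

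Other pituitary lists that stood apart as lower were the cell cycle (median -0.55, 12 genes, 3 at least 2-fold lower, TOP2A at -1.44 and AURKB at -1.23), T and B lymphocytes (-1.07, 9 genes, 5 at least 2-fold lower, CD2 at -1.07 but CD79A at 0.76), heat shock proteins (-0.45, 8 genes, HSPH1 at -1.17) and extracellular matrix (-0.23, 14 genes, COL3A1 at -0.84 but TIMP1 at 0.91). The insulin-like growth factor list did so as well (-0.36, 10 genes), with IGFBP1 at -2.47 and IGFBP5 at 1.23. Among lists not assigned to the pituitary, ovulation genes were lower (median -0.92, 9 genes, percentile 0.01). Smooth muscle genes, also not assigned to it, were higher (0.83, 5 genes, percentile 99.9). Immediate early genes were lower at the median (-0.32, 15 genes, percentile 0.21), with NR4A3 at -1.89 and ATF3 at -1.63, but the median was 0.016 when genes below a mean of 200 were left out. Interferon-stimulated genes (-0.26, 16 genes, percentile 0.47), with OAS1 at -1.42, lost their place apart at that floor (-0.06). Endothelial genes were higher at the median (0.39, 9 genes, percentile 99.9), with KDR at 0.94, although CLDN5 was at -0.86. Neuron (-0.13), astrocyte (-0.10), myelin (-0.0039), microglia (-0.26), cholesterol (-0.14), MHC class II (0.25), unfolded protein response (-0.06) and glycolysis lists (-0.09) lay inside the random range. Neurons had a lower median of -0.26, outside it, with either other floor, and microglia one of -0.49 with no floor.

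Over the floor of 50 there were 10720 pituitary genes, 129 of them at least 2-fold higher and 204 at least 2-fold lower. Making the totals equal moved the log2 folds by -0.12 and gave 98 and 277. Among genes with a symbol, those higher by the most were C14H10orf116 (1 and 1049 reads, 1112-fold, interval 199 to 43948), SNCG (0 and 387 reads, at least 137-fold), the melanogenic enzyme gene TYRP1 (29 and 268 reads), SMARCC2 (55 and 496), UGT2A3 (log2 fold 3.03), COLGALT2 (2.61), FRMPD1 (2.22), FSHB, MYC (1.91) and NR0B1 (1.90). Those with a symbol that were lower by the most were the fucosyltransferase gene FUT2 (109 and 0 reads, at least 34.3-fold), the phosphatase gene DUSP2 (2706 and 130 reads, 19.6-fold, interval 16.5 to 23.6), UCP3 (368 and 39), FA2H (log2 fold -2.92), SYTL1 (-2.85), B2M (-2.84), B3GNT5 (-2.47), IGFBP1 (1521 and 259 reads), TUBA1C (-2.40) and ALOX15 (-2.40). In the authors' deposited table, 100 pituitary genes had an adjusted p of at most 0.05. Adjusted p in the authors' deposited table was 0.000128 for FSHB, 2.81e-07 for AVPR1B, 0.248 for GNRHR and 1 for POMC.

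In the ovary, genes of steroid synthesis, granulosa cells and oocytes were lower, and MHC class II and glycolysis genes were higher. STAR (ENSSSCG00000026109), which carries cholesterol into mitochondria, gave 50383 reads in estrus and 1966 in anestrus and was 23.6-fold lower (22.6 to 24.8). CYP17A1, which makes androgens, gave 64699 and 4202 reads and was 14.2-fold lower (13.8 to 14.7). CYP19A1 (aromatase), which makes estrogens, gave 8994 and 1148 reads and was 7.23-fold lower (6.80 to 7.69). HSD3B1, which makes progesterone from pregnenolone, went the other way, with 10245 and 49378 reads, and was 5.22-fold higher (5.11 to 5.34). MMP13, a collagenase gene, gave 4 reads in estrus and 11902 in anestrus and was 3225-fold higher (1259 to 11837). Phagocyte and lysosome genes, a list added after the data were seen, were higher in 16 of 16 (median log2 fold 1.84, percentile 100).

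Of 11 genes of ovarian steroid synthesis, 8 were at least 2-fold lower and 1 higher (median log2 fold -1.89, below all random lists). The gonadotropin receptor genes LHCGR (4.76-fold lower, 4.27 to 5.33) and FSHR (2.05-fold lower, 1.74 to 2.41) were both lower. Granulosa cell genes were lower in 10 of 10, 7 of them at least 2-fold (median -1.38, below all random lists). INHA, the inhibin alpha subunit, gave 86346 and 14495 reads and was 5.50-fold lower (5.40 to 5.59), whereas INHBA was 1.24-fold lower (1.19 to 1.29). SERPINE2 and FOXL2 were at -2.39 and -1.70. Theca and luteal genes had a median of -1.89 over 7 genes, 5 at least 2-fold lower and 2 at least 2-fold higher, HSD3B1 among these. STAR, CYP17A1, INSL3 and HSD3B1 are also in the steroid synthesis list, and INSL3 set the median of both. The granulosa list shares CYP19A1 and HSD17B1 with steroid synthesis, so these lists are not independent. Oocyte genes were lower in 11 of 11, 8 at least 2-fold (median -1.64, below all random lists), with the zona pellucida genes ZP2 at -2.25 and ZP3 at 1033 and 238 reads and the oocyte growth factor gene BMP15 at -2.08. Cholesterol synthesis and uptake genes were at least 2-fold lower in 10 of 15 (median -1.46, below all random lists). HMGCS1, an enzyme gene of cholesterol synthesis, was at -2.16. Steroid receptor genes had a median of -0.71 (8 genes, percentile 1.02), with ESR1 at -2.21 and PGR 2.31-fold lower (1.61 to 3.35). That list fell inside the random range with a floor of 200 (-0.43). ESR2 had 5 and 3 reads, too few to show a difference.

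MHC class II genes were at least 2-fold higher in 7 of 7 (median 1.90, percentile 99.98), with SLA-DRB1 at 2.49 and CIITA, the transactivator of these genes, at 1.90. Hypoxia and glycolysis genes were at least 2-fold higher in 6 of 11 (median 1.03, percentile 99.8), led by the hexokinase gene HK2 (46 and 1537 reads, log2 fold 5.15) and LDHA (2.66). The 3 lower members were ADM (-0.72), CA9 (-0.60) and VEGFA (-0.36). Apoptosis genes had a median of 0.53 (10 genes, percentile 98.2), with FAS at 1.56 and BAX at 0.94, and fell inside the random range with a floor of 200 (0.35). Ovulation genes had a median of 0.63 (13 genes, percentile 97.7), but 5 were at least 2-fold higher and 6 at least 2-fold lower. The hyaluronan synthase gene listed as SHAS2 gave 2 and 120 reads (65.0-fold, interval 17.6 to 543), RUNX1 was at 1.75, and CTSL and PTX3 were at -1.82 and -1.58. The median of this list was -1.37 with a floor of 200, and it lay inside the random range with a pseudocount of 5 (0.55) or a trimmed mean (0.632). Macrophage genes had a median of 0.66 (8 genes, percentile 96.7), with CSF1R at 3.90 (median 0.11 without this gene), CX3CR1 at 2.77 and AIF1 at 2.26 but C1QA at -0.19, and lay above the random range with a floor of 200 (1.74). Extracellular matrix genes did not stand apart (median 0.35, 14 genes, percentile 85.2), but FN1 (fibronectin) was at 5.13, TIMP1 at 4.04 and POSTN at 3.50, and COL6A3 was at -0.97. The unfolded protein response list lay just inside the range (0.59, 10 genes, percentile 97.0), with TRIB3 at 4.53.

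Immediate early genes (median -0.71, 13 genes, EGR1 at -2.89 and FOS at -2.12), smooth muscle genes (-0.75, 6 genes, ACTG2 at -2.44 but ACTA2 at -0.47) and the insulin-like growth factor list (-0.50, 11 genes, IGFBP6 at -1.63 but IGF2R at 1.64) stood apart as lower in the ovary. Epithelium and oviduct genes did so too (-2.05, 7 genes), with OVGP1 (oviduct glycoprotein) at -2.72 and KRT8 at -2.05 but EPCAM at 2.31 and CLDN4 at 2.07. Cell cycle genes were lower at the median (-0.45, 13 genes, percentile 2.22), AURKB at -1.22. They lay inside the random range with a floor of 200 (-0.38) or a pseudocount of 5 (-0.39). Activin and inhibin (-0.23), endothelium (0.01), T and B lymphocyte (-0.08), interferon (-0.06) and heat shock lists (-0.29) lay inside the random range.

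The ovary had the widest spread of log2 folds (SD 0.98 across 10902 genes over the floor, against 0.42 in the hypothalamus and 0.45 in the pituitary). In it, 1343 genes were at least 2-fold higher and 867 at least 2-fold lower. Making the totals equal moved the log2 folds by -0.20 and gave 1033 and 1242, so that which direction held more genes depended on the scaling in the ovary and the hypothalamus. Among genes with a symbol, those higher by the most after MMP13 were SNCG (0 and 466 reads, at least 168-fold), the calgranulin genes S100A12 (10 and 3401 reads), S100A9 (6 and 997) and S100A8 (7 and 635), the bile acid enzyme gene CYP7A1 (1 and 439 reads, 476-fold, interval 84.9 to 18833), PPP1R11 (0 and 150 reads, at least 54.2-fold), SLC1A1 (2 and 202), MSMB (692 and 44848) and BDNF (3 and 244). Besides STAR and CYP17A1, those with a symbol that were lower by the most included SQRDL (226 and 0 reads, at least 69.5-fold), the sulfotransferase gene SULT1C3 (2205 and 21 reads), C1QL4 (196 and 8), RDH12 (3039 and 140), CRABP1 (log2 fold -4.00), CITED1 (-3.72) and AGR2 (-3.67). In the authors' deposited table, 108 ovarian genes had an adjusted p of at most 0.05. Adjusted p in the authors' deposited table was 3.68e-12 for MMP13, 0.18 for STAR, 0.538 for CYP17A1 and 1 for HSD3B1.

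**Figure D2:**
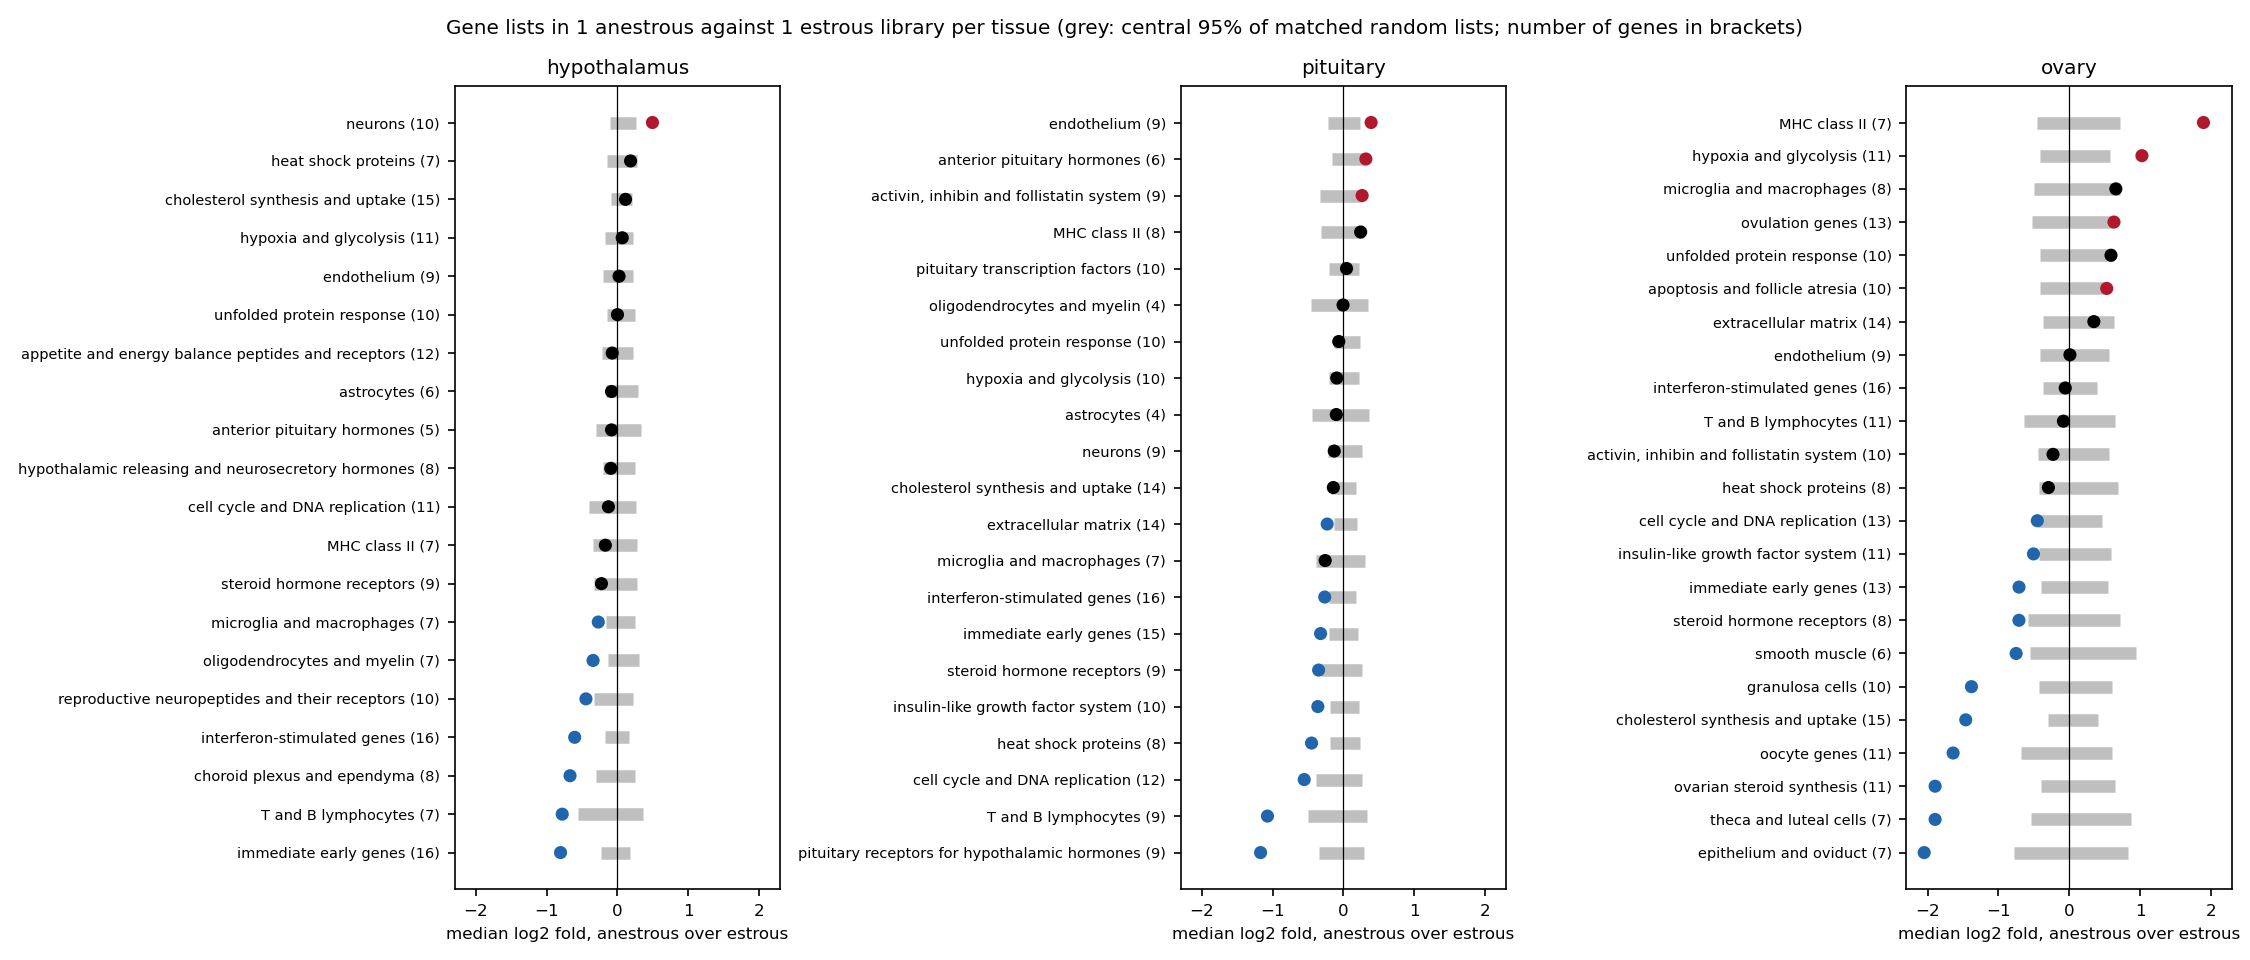
Median log2 fold (anestrous over estrous library, x axis) of each gene list in the 3 tissues, with the number of measured genes in brackets. Grey bars are the central 95% of random lists matched on expression; red points lie above and blue points below it, such as MHC class II (1.90) and ovarian steroid synthesis (-1.89) in the ovary.

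Across tissues, 12 genes were at least 2-fold higher in all 3 and 4 at least 2-fold lower in all 3, where independent lists would share 0.034 and 0.054 genes. The tissues of a state are not replicates and may come from the same sows. An excess over independent lists, here and for pairs of tissues, therefore need not come from the state. With equal totals, 7 were lower in all 3. The higher ones with a name were SNCG (gamma-synuclein), SMARCC2 (a chromatin remodelling subunit), RAB11FIP5, CSF1R (the receptor of macrophage colony-stimulating factor), the mitochondrial gene ND2, SLA-DRB1 and CPQ. The lower ones with a name were TUBA1C, the mitochondrial gene ATP8 and an MHC class I gene listed as TMP-SLA-2. SMARCC2 was higher by log2 folds of 2.60, 3.23 and 2.52 in hypothalamus, pituitary and ovary, and TUBA1C lower by -3.83, -2.40 and -3.34. ND2 was at 1.14, 1.52 and 1.52 and ATP8 at -1.13, -1.71 and -1.10. Hypothalamus and pituitary shared 20 higher genes (0.776 for independent lists) and 12 lower genes (1.11). Hypothalamus and ovary shared 25 higher (7.91) and 26 lower (5.77), and pituitary and ovary 27 higher (7.43) and 32 lower (10.1). With equal totals these counts were 13 for higher in hypothalamus and ovary, 21 for lower in hypothalamus and pituitary, and 52 for lower in pituitary and ovary. Genes that differed in opposite directions also outnumbered independent lists in most pairings, so the excess is partly one of genes that differ in any direction. They numbered 4 (1.24) for hypothalamus higher and pituitary lower, 0 (0.699) for the reverse, 11 (4.90) and 16 (9.32) for hypothalamus and ovary, and 16 (5.24) and 25 (14.3) for pituitary and ovary. Across 10100 genes, which are not independent replicates, log2 folds in hypothalamus and pituitary had a Pearson r of 0.28 (0.193 with no floor and 0.177 with a floor of 200) and a Spearman rho of 0.13. For hypothalamus and ovary r was 0.03 and rho -0.03, and for pituitary and ovary 0.03 and -0.05.

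**Figure D3:**
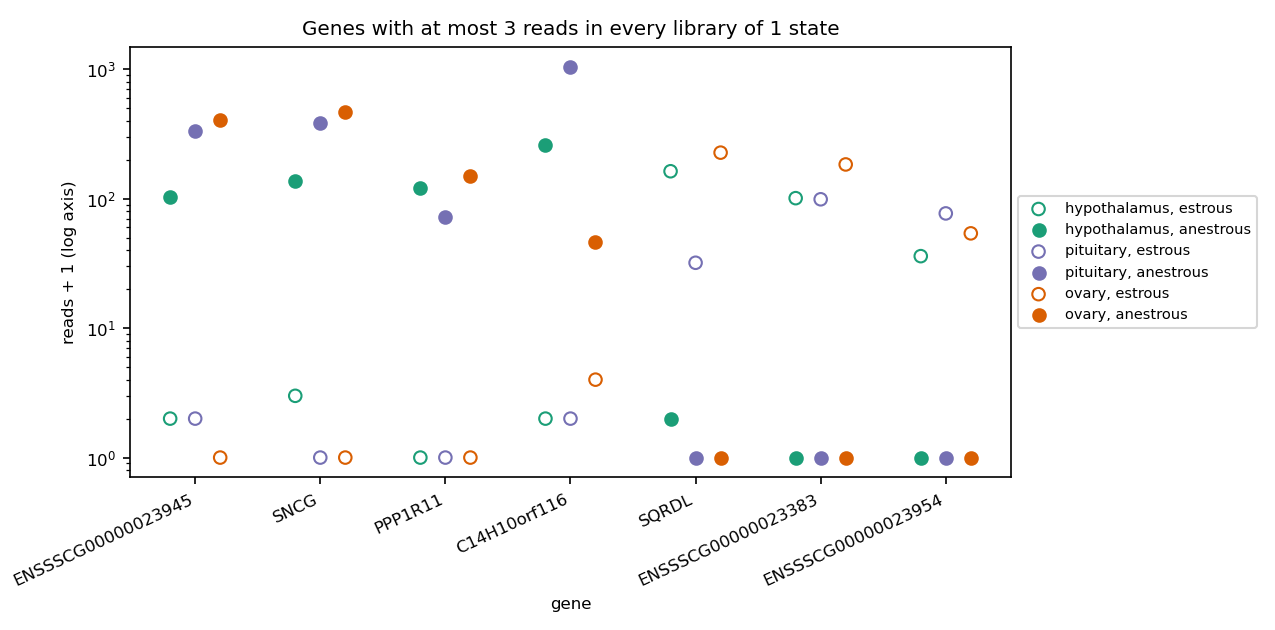
Reads plus 1 on a log axis in each of the 6 libraries for 7 genes. These had at most 3 reads in every library of 1 state and a normalised count of at least 50 in at least 2 libraries of the other. Open circles are estrous and filled circles anestrous libraries; SNCG had 2, 0 and 0 reads in the estrous and 137, 387 and 466 in the anestrous hypothalamus, pituitary and ovary libraries.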

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

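No test was run for this part, so none was chosen after its result was seen. MX2, an interferon-stimulated gene, was the only gene named by the fixed rule in more than 1 tissue, and over the floor of 50 there, that was at least 2-fold lower in 1 tissue and at least 2-fold higher in another. Its log2 fold was -1.22 in the pituitary (172 reads in estrus and 69 in anestrus) and 2.004 in the ovary (113 and 421 reads). The difference between the tissues was not tested, since each has 1 library per state.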

How the results depend on the processing

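Leaving out the hypothalamus libraries and the count tests with edgeR and DESeq2 were chosen after the data were seen, as were the lists without genes that differed alike in all 3 tissues. No paired analysis was possible because the labels give no replicate numbers and each tissue has 1 library per state; the count tests pair libraries by tissue only. Of 987 recomputed folds of named genes, 872 stayed within the counting interval and 115 moved outside it, 103 of them with equal library totals. Of 371 recomputed list medians, 356 kept their place relative to the random range, 9 moved inside it, 4 moved outside it and 2 turned sign. Those 2 were, with a floor of 200, the pituitary immediate early genes (0.016) and the ovulation genes (-1.37). Fewer genes enter at that floor, and the cause was not tested further. Removing the genes that differed alike in all 3 tissues could move only the macrophage and MHC class II lists, which hold CSF1R and SLA-DRB1, and neither crossed the range, although the macrophage median in the ovary was then 0.11 in place of 0.66. Counts depended on the floor by its construction. With no floor, higher and lower genes numbered 845 and 877 in the hypothalamus, 965 and 1139 in the pituitary, and 2534 and 2223 in the ovary. Shared genes then numbered 51 higher and 67 lower in all 3 tissues, 154 and 200 in hypothalamus and pituitary, 203 and 245 in hypothalamus and ovary, and 220 and 256 in pituitary and ovary. With a floor of 200 the tissue counts were 75 and 29, 48 and 84, and 880 and 501. The shared counts were then 4 higher in all 3, 7 and 5 in hypothalamus and pituitary, 9 and 10 in hypothalamus and ovary, and 13 and 13 in pituitary and ovary. The correlation of hypothalamus and pituitary folds was 0.193 with no floor and 0.177 with a floor of 200. Asking also for an adjusted p of at most 0.05 in the authors' deposited table left 67 and 31, 36 and 50, and 92 and 15. Equal totals moved 4 shared counts by over 1.5 times, to 13 higher in hypothalamus and ovary, 7 lower in all 3, 21 lower in hypothalamus and pituitary, and 52 lower in pituitary and ovary, because that scaling moves all folds down. Without the hypothalamus, 27 genes were higher and 32 lower in the other tissues. For genes such as NPY, AGRP and PGR in the hypothalamus and ESR2 in the ovary, a few reads set the ratio, and why they were few was not tested. With the tissues as replicates, edgeR called 0 genes at an adjusted p under 0.05 among 14444 (542 at an unadjusted p under 0.05), and DESeq2 called 49 (24 higher and 25 lower).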

Other observations

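Of the tests in this part, the comparison of hypothalamic transcription factors with the neuropeptide genes, the tests on mitochondrial genes, the other pairings of libraries, the comparison of ovarian cell types, the count test with the tissues as replicates and the scan of pathways were chosen after their results were seen. The lists of thalamus markers, hypothalamic transcription factors and phagocyte genes were added after the data were seen, but before their own values were looked at. In the ovary, 99 of 267 pathways annotated in the deposited tables had a median above the central 95% of matched random lists and 21 one below it, where random lists give 6.68 on each side. Pathways share genes, so these counts are not independent. Phagosome genes had a median log2 fold of 0.85 (89 genes, 40 at least 2-fold higher), lysosome genes 0.89 (82 genes, 37 higher) and rheumatoid arthritis genes 1.23 (51 genes). Ovarian steroidogenesis (-0.96, 27 genes), ribosome (-0.37, 86 genes) and spliceosome genes (-0.26, 83 genes) lay on the other side. In the hypothalamus, 34 of 268 pathways were high and 65 low. Retrograde endocannabinoid signalling (0.31, 63 genes), glutamatergic synapse (0.17, 75 genes) and GABAergic synapse (0.18, 52 genes) were among the high ones, and TNF signalling (-0.21, 69 genes) and Toll-like receptor signalling (-0.22, 67 genes) among the low ones. In the pituitary 5 of 266 were high and 24 low, among these ECM-receptor interaction (-0.17, 46 genes).

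Lower AVP, OXT, POMC and KISS1 in the anestrous hypothalamus library raised the question of which part of the region each dissection held. Carry-over of pituitary with the proportions of PRL, GH1 and POMC found in the estrous pituitary library is argued against. PRL and GH1 gave 1479 and 656 reads in the estrous hypothalamus library and 1598 and 647 in the anestrous one. Their excess was -1.16% of the 15391 normalised counts that the POMC excess would bring. Pituitary tissue with much POMC but little PRL and GH1 would escape this test. A lower share of neurons was also considered, but neuron markers were higher (median 0.49). A lower share of the whole hypothalamus is argued against as the only cause for these 4 genes. The 15 measured hypothalamic transcription factors had a median log2 fold of -0.14 and none lay below -1.35, against -2.50 for KISS1. The list fixed for pituitary transcription factors was lower here in 6 of 6 genes (median -0.69, percentile 0.15), with SIX6 at -1.42, TBX19 at -1.28 and ISL1 at -1.04. These values lie above -2.50 too, but they leave a partly lower share open. Since the list was fixed for pituitary factors, pituitary tissue that escapes the test above stays open as well. Thalamus markers, all 14 of which also had reads in the estrous library, stood above all random lists (percentile 100, median 0.85, CALB2 at 1.24 and CACNA1G at 1.42). The 15 hypothalamic transcription factors were at percentile 30.2. A dissection that reached further into the thalamus or missed some hypothalamic nuclei therefore cannot be told apart from a difference in expression with state. Only 1 library stands for each state, and both may hold.

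For 7 genes, every library of 1 state had at most 3 reads while libraries of the other state reached a normalised count of 50 in at least 2 tissues: SNCG, PPP1R11, C14H10orf116 and an unnamed gene were near absent in estrus, and SQRDL and 2 unnamed genes in anestrus. Dropout in single libraries is argued against, since the other 3 ways of pairing 1 library per tissue gave 0 such genes. The mitochondrial share of reads was higher in each anestrous library (17.8% and 20.6%, 4.198% and 5.091%, 4.35% and 5.91%), with 11, 10 and 12 of 13 genes higher, and beyond ND2 and ATP8, seen beforehand to differ alike, their log2 folds ranged over at least 0.94 in each tissue, which does not decide for or against RNA quality. Without ND2 and ATP8 these folds were still alike between tissues (lowest Pearson r 0.751, highest 0.839, across 11 genes that are not independent replicates; lowest 0.944 with them). Sequence differences between the sows of the states would give such folds, and may also make reads of the 7 genes map in 1 group only. Any other difference shared by all libraries of a state could give them too, and the design cannot separate it from state. The likeness of the folds is thus only indirect evidence for the 7 genes. RNA quality and a difference with state, the latter untested, stay open.

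In the anestrous ovary library, steroid and follicle genes were lower while phagocyte and lysosome genes were higher. A lower share of steroid-producing and follicle cells alone would leave the other cell types higher alike. The medians of endothelium, smooth muscle, lymphocyte and macrophage lists lay 1.41 apart, from 0.66 for macrophages to -0.75 for smooth muscle. This distance alone is weak, since the macrophage median was 0.11 without CSF1R, near endothelium (0.01) and lymphocytes (-0.08). The phagocyte median of 1.84, from a list without CSF1R, lies far from endothelium and lymphocytes. It argues against that explanation for the phagocyte and lysosome genes only. A higher level per cell would raise these genes too, so they do not settle the shares of the cell types. More blood is argued against, since HBB was at 0.344 of its estrous count (interval 0.297 to 0.396). More phagocytes remain a candidate explanation for the higher part: 16 of 16 phagocyte and lysosome genes were higher, 12 at least 2-fold, and their median stood above all random lists (percentile 100), with CTSB at 108331 reads against 35518, APOE at 73747 against 18511 and SPP1 at 39285 against 3238. Not all such markers followed: MRC1, 1 of the 16, was at a log2 fold of 0.21. Of the 8 macrophage genes, 4 were at least 2-fold higher, while C1QA, C1QB, C1QC and P2RY12 were at -0.19, 0.11, 0.06 and -0.0038. All 16 phagocyte and lysosome genes also had reads in the estrous ovary. A higher level per cell, and an effect of state on both groups of genes, stay open and untested.

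With the tissues taken as replicates, edgeR called 0 genes by state in the real grouping (542 at an unadjusted p under 0.05, and 49 by DESeq2). The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and a real count of 0 leaves nothing for the splits to test. The highest other count was 1457. It came from both splits that put the hypothalamus libraries on 1 side and the pituitary libraries on the other. There the model with a tissue term reduces to the difference of the ovary libraries. This count is thus that of 1 ovary library against 1, with the spread taken from the other tissues.

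The unnamed gene ENSSSCG00000003151 was chosen after its values were seen. In the pituitary it gave 64427 reads in estrus and 120446 in anestrus.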
